A study of Mus musculus with 6 samples.

How the data were processed

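Central nervous system-associated macrophages (CAMs), the macrophages that line the borders of the brain in the perivascular spaces, meninges and choroid plexus, were profiled by RNA sequencing in male C57BL/6 mice. Per the labels' protocols, cells lacking CD3 and carrying CD11b, CD45 and CD206 were sorted from whole brains. About 500 pg of total RNA per sample was turned into cDNA with a low-input template-switching kit. The cDNA was amplified over 13 PCR cycles, made into libraries by tagmentation and sequenced as single reads. This kit does not mark the strand of a transcript. Genes that overlap on opposite strands, and near-identical copies such as H2-Q6 and H2-Q7 or H2-DMb1 and H2-DMb2, were therefore treated as uncertain. Of the genes named here, H2-DMa, Ciita, Ctsb, Ppt1, Cd81, P2ry12, P2ry13, Csf1r, Folr2, Lat2, Bco2 and Ccdc152 overlap another tested gene on the opposite strand, and that gene was at the higher level in at least 1 age group for Lat2, Bco2 and Ccdc152. The 6 libraries were grouped by the age in the labels into 3 young libraries (2 months) and 3 aged libraries (18 months). The labels do not say whether the libraries of a group came from separate animals, so p-values measured only the spread between these libraries, which may be technical.

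Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, and FastQC, fastp, DRAGEN and Picard were used with the mm10 build. The role of each tool and the annotation release are not given in the sources used here. Each deposited table held, per the file headers, the estimated count of reads per gene, TPM (scaled by the authors for depth and effective length) and the effective length, a value that was not used. The estimated counts were not scaled to depth, and 90.2% to 92.9% of them were whole numbers. They were rounded to whole numbers here, which changed a library's total by at most 9e-05%. Each table listed 35598 gene identifiers, of which 35513 matched the GENCODE M21 annotation of the same build when the version was ignored. Symbols and coordinates were taken from that annotation. A symbol carried by more than 1 identifier was kept for the identifier with the most reads, and the other 45 identifiers were listed by identifier.

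Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group at its defaults, libraries were scaled by TMM, and a quasi-likelihood F test with robust dispersion compared aged with young libraries with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 10661 genes tested, and a gene was called at an adjusted p under 0.05. The heterogeneity test and the comparison with random lists used the upper tail only, and all other tests were two-sided. Levels are TMM-normalized CPM, given as mean ± SD over 3 libraries. Log2 fold changes are aged minus young with a standard error (SE). The SE was calculated back from the test, as the absolute log2 fold change over the square root of the F statistic. A count of 0 was bounded by a floor of 3 counts per library. Such bounds cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

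Before the data were examined, 36 gene lists were fixed. They covered the sort markers, antigen presentation, interferon and cytokine responses, chemokines, adhesion, CAM identity, metabolism, stress and the markers of other cell types. The design, the alternative settings and the rule for naming genes were fixed at the same time. Lists with at least 5 measured members (33 lists) were tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives; fry tests whether the genes of a list move on balance in 1 direction, with no comparison with other genes. Within each list, member p-values were also adjusted over the list alone.

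The naming rule took the sort markers, the 10 called genes with the largest change in each direction with a mean of at least 10 CPM and no overlap between groups, up to 3 called members of each list in each direction, and the 2 most abundant members of a list with none. With fewer than 10 calls, it added the 10 genes with the smallest p-values. Members that passed adjusted over their list alone, genes called under the alternative with a mean of at least 50 CPM, Cd209d and Ccdc152, and other list members given to show a list's range, were chosen for mention after their values were seen. Some genes that the rule or these choices took are not reported here.

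The alternative settings were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom with and without library quality weights, limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, no filter, a filter of 10 CPM in 3 libraries, non-robust dispersion, a block on the replicate number, a limit of 1 on the absolute log2 fold change, and leaving out each library in turn. A filter on a mean of at least 50 CPM was added after the data had been seen. The fitting code was tested on simulated counts drawn from the means, spread and sizes of these libraries with known genes changed. In the simulated comparison of aged with young libraries (10081 genes tested), the main test recovered 0% of 25 genes of at least 50 CPM changed 2-fold, 28% at 4-fold, 80% at 8-fold and 92% at 16-fold, with 0 false calls. Of 25 genes under 50 CPM it recovered 0% at 2-fold and 4-fold, and 12% at 8-fold and at 16-fold.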

Results

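The series compared CAMs from young and aged mice and its title places the comparison in work on the immune response after stroke in old animals. The libraries held no stroke group, so the question addressed was how the transcripts of sorted CAMs differ between 2 and 18 months of age. The 3 young libraries held 33306121, 26605079 and 28302394 counts and the 3 aged libraries 30596574, 32902652 and 30044365. Between 9875 and 12543 genes had at least 5 counts in a library. Libraries of the same group correlated at 0.589 to 0.688 in log2 CPM, across genes, which are not independent replicates, and libraries of different groups at 0.570 to 0.659. Of the 6231 genes with a mean of at least 10 CPM, 13.2% had 3 counts or fewer in some library, against 0.868% of the 2189 genes with a mean of at least 50 CPM. The median biological coefficient of variation was 129% below 50 CPM and 48.2% from 50 CPM upward.

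The chemokine gene Cxcl13, which encodes a ligand that attracts B cells, was detected in every aged library and in no young one. The gene (ENSMUSG00000023078.6, mm10 chromosome 5, 95956951 to 95961068) had 0 counts in each young library and 5997, 4524 and 4356 counts in the aged libraries. Its aged level was 160 ± 45.9 CPM (SD, n = 3), at least 1432-fold higher than the highest floor of the young libraries (0.112 CPM, 3 counts per library). Cxcl13 was the 1 gene of 10661 called by edgeR's quasi-likelihood test (adjusted p = 0.00439), and 0 genes were called lower. At an unadjusted p under 0.05 there were 387 higher and 218 lower genes, where chance alone gives 533, and the next smallest adjusted p was 0.378. By age 605 genes lay under that limit, and other splits of the 6 libraries into 3 and 3 gave 233 to 357. The splits are too few for a test. The call ended without aged replicate 2 (adjusted p = 0.117) or aged replicate 3 (adjusted p = 0.0514), and in limma-voom without (adjusted p = 0.117) and with (adjusted p = 0.0755) library quality weights. The DESeq2 Wald test called 270 genes higher and 187 lower, edgeR without a low-count filter called 51 and 11, and edgeR on genes with a mean of at least 50 CPM, a filter chosen after seeing the data, called 19 and 6.

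Genes of MHC class II antigen presentation, which load peptides for CD4 T cells, were higher in the aged libraries. Adjusted over the list alone, 6 of the 13 measured members rose and 0 fell; over all genes tested, 0 members passed. Cd74, the invariant chain that escorts class II molecules, rose from 2359 ± 542 to 9773 ± 4051 CPM (n = 3 each, log2 fold change 2.05, SE 0.37, edgeR adjusted p = 0.00117 over the list alone and 0.378 over all genes). The class II chain genes H2-Eb1, H2-Ab1 and H2-Aa rose by 2.01 (SE 0.33), 1.79 (SE 0.44) and 1.60 (SE 0.34) on the log2 scale over the list alone. H2-DMa, part of the peptide exchange factor, rose by 2.10 (SE 0.36) and the protease gene Ctss by 0.89 (SE 0.27). All 6 were higher in each aged library than in any young one, as was 1 further member, Lgmn. So 7 of 13 members did not overlap between groups, all with aged higher, where chance gives 10% over both directions together. Of the 2189 genes with a mean of at least 50 CPM, 19.6% did not overlap in either direction, and 245 were higher in each aged library. Some class II members, such as Ciita, lay under 50 CPM. H2-DMb1 (log2 fold change 2.17, SE 0.85), Ciita (1.56, SE 1.85), Ifi30 (0.45, SE 0.40) and H2-Oa (-0.20, SE 1.83) did not pass. In the fit restricted to a mean of at least 50 CPM, Cd74, H2-DMa, H2-Eb1, H2-Aa and H2-Ab1 were called.

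In mm10, Cd74 (ENSMUSG00000024610.15) lies on chromosome 18 from 60803848 to 60812652. On chromosome 17, H2-DMa spans 34119541 to 34139101, H2-Ab1 34257689 to 34269419, H2-Aa 34282744 to 34287823 and H2-Eb1 34305867 to 34316674. As a list, class II presentation was called higher by camera (median log2 fold change 1.79, adjusted p = 0.000109), with an adjusted p = 0.440 with an estimated correlation and 0.198 by fry. The summed level of microglia markers was also higher in each aged library than in any young one.

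**Figure D1:**
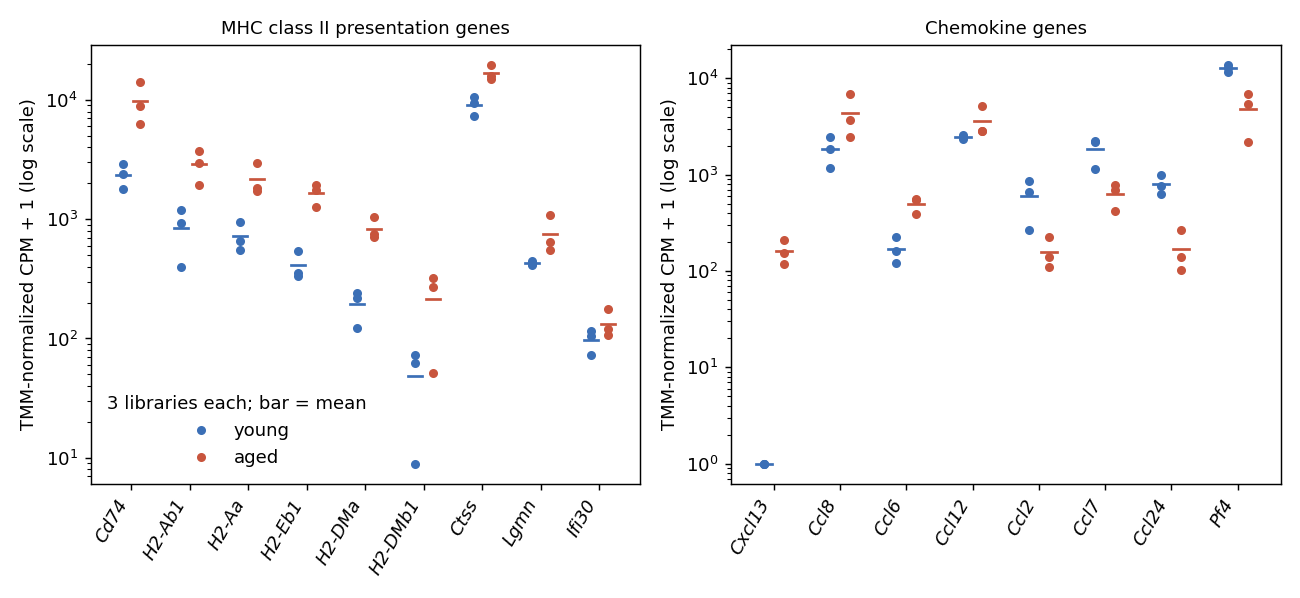
TMM-normalized CPM plus 1 on a log scale for 9 genes of MHC class II presentation (left) and 8 chemokine genes (right), with 1 point per library, blue for young and red for aged, and bars at the group means of 3 libraries. Cd74, H2-Ab1, H2-Aa, H2-Eb1, H2-DMa, Ctss and Lgmn lie higher in each aged library than in any young one, and Cxcl13 lies at 0 CPM in the 3 young libraries.

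Other chemokine genes differed in both directions. Adjusted over the list alone, 3 of 21 measured chemokine and receptor genes rose (Cxcl13, Ccl6 and Ccl8) and 4 fell (Ccl2, Ccl7, Ccl24 and Pf4), and only Cxcl13 passed over all genes tested. Ccl24, an eosinophil attractant, fell from 795 ± 191 to 168 ± 87.5 CPM over the list alone (log2 fold change -2.24, SE 0.42). The monocyte attractants Ccl2 and Ccl7 fell by 1.92 (SE 0.48) and 1.55 (SE 0.37) on the log2 scale over the list alone. Pf4, a platelet factor gene abundant in CAMs, went from 12703 ± 1185 to 4772 ± 2369 CPM. Ccl8 rose by 1.25 (SE 0.43) and Ccl6 by 1.56 (SE 0.35), both over the list alone. The chemokine list as a whole was not called by camera (median 0.76, also with Cxcl13 at its bound, adjusted p = 0.172).

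MHC class I presentation was called higher by camera (median log2 fold change 1.22 over 19 members, adjusted p = 1.59e-05; adjusted p = 0.112 with an estimated correlation and 0.00241 by fry). Over the list alone 1 member passed, H2-Q7, at 0.148 ± 0.0645 CPM in young and 30.8 ± 22.5 CPM in aged libraries. It is a near copy of other class I genes, so its reads are uncertain. Fitted values were above 0 for 18 of 19 members, but 0 passed over all genes tested, and the most abundant member, B2m, was at 23167 ± 2505 and 22655 ± 7703 CPM. The type I interferon list was called higher (median 0.56 over 29 members, adjusted p = 0.0353; adjusted p = 0.440 with an estimated correlation), with 0 members past over the list alone. Its call ended without young replicate 1 (adjusted p = 0.269) or aged replicate 1 (adjusted p = 0.339), at a mean of at least 50 CPM (adjusted p = 0.0588) and by fry (adjusted p = 0.289). Its 2 most abundant members were Ly6e, at 2878 ± 123 and 5332 ± 230 CPM, and Ifitm3, at 960 ± 118 and 1686 ± 608 CPM. The interferon gamma list was called higher (median 0.91 over 20 members, adjusted p = 0.0353; adjusted p = 0.385 with an estimated correlation), with 0 members past over the list alone, among them Gbp7 at -0.60 (SE 0.54) and Ifi47 at 0.07 (SE 0.42). Without single libraries (young replicates 1 or 3, aged replicates 2 or 3) its adjusted p lay between 0.0679 and 0.109, and the call also ended at a mean of at least 50 CPM (adjusted p = 0.238), by fry (adjusted p = 0.124) and with a replicate block (adjusted p = 0.0665).

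Microglia markers, from brain macrophages that the gate should take only if they carry CD206, were present in all libraries and higher in the aged ones. The microglia receptor gene P2ry12 was at 833 CPM or more in every library. Over the list alone 6 of 19 members rose, among them P2ry12, P2ry13, Siglech, Sparc and Olfml3. P2ry12 rose from 1133 ± 263 to 2661 ± 997 CPM. Fcrls (-0.35, SE 0.29), Csf1r (-0.07, SE 0.29) and Tgfbr1 (0.06, SE 0.37) did not pass. Camera called the list higher (median 1.16, adjusted p = 0.00065; adjusted p = 0.440 with an estimated correlation and 0.0960 by fry). The summed level of its genes was 9678, 8261 and 10137 CPM in the young libraries and 13084, 20747 and 16953 CPM in the aged ones.

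Genes that mark CAMs summed to lower levels in each of the same aged libraries. The sum was 34872, 37176 and 33606 CPM in young and 23617, 13460.5 and 20986 CPM in aged libraries. Its largest member in every library was Pf4 (12703 ± 1185 and 4772 ± 2369 CPM). Fitted values were above 0 for 9 of the 30 members, so the sum does not show a loss shared by all of them. Over the list alone 2 of 30 members fell and 0 rose. Dab2, an endocytic adaptor, fell from 1322 ± 107 to 576 ± 148 CPM, and Ednrb, an endothelin receptor, from 164 ± 92.5 to 23.3 ± 19.3 CPM. Mrc1, which encodes the CD206 used in the gate, was at 2795 ± 135 and 1611 ± 639 CPM (log2 fold change -0.79, SE 0.32, edgeR adjusted p = 0.817), and Ms4a7 at 5488 ± 249 and 2873 ± 1401 CPM, neither past. Cbr2 (0.07, SE 0.27), Folr2 (-0.06, SE 0.32) and Cd163 (-0.02, SE 0.39) lay near 0. Cd209d (2.54 ± 4.40 and 115 ± 52.6 CPM), Cd209b (29.7 ± 28.2 and 82.6 ± 19.4 CPM) and Timd4 (84.8 ± 33.6 and 168 ± 47.6 CPM) were higher in each aged library than in any young one, but did not pass over the list alone. The list was not called (median -0.47, camera adjusted p = 0.0532). It was called lower with the filter of 10 CPM in 3 libraries (adjusted p = 0.0110), at a mean of at least 50 CPM (adjusted p = 0.00722) and without aged replicate 1 (adjusted p = 0.0398). The gate markers Ptprc (CD45) at 317 ± 14.8 and 385 ± 180 CPM, and Itgam (CD11b) at 82.9 ± 15.2 and 81.7 ± 22.1 CPM, did not pass. Of the T cell genes the gate excludes, Cd3e was too low to be tested, Cd3d was at 2.07 ± 3.56 and 22.7 ± 32.1 CPM, and Cd3g at 14.4 ± 14.6 and 22.2 ± 38.3 CPM. The aged means of both rested mostly on aged replicate 1 (59.4 CPM for Cd3d and 66.5 CPM for Cd3g). In aged replicate 3 they were at 0.0353 and 0.0707 CPM.

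The genes of lipid handling and disease-associated microglia were called higher as a list (median 0.65 over 20 members, camera adjusted p = 0.00192; adjusted p = 0.385 with an estimated correlation). Over the list alone 0 of them passed. Apoe, the lipid carrier, was at 15262 ± 2085 and 24318 ± 3824 CPM and the cathepsin gene Ctsb at 2381 ± 402 and 4838 ± 1523 CPM, each without overlap between groups. The call ended without aged replicate 3 (adjusted p = 0.0983). The lysosome list was called higher (median 0.37 over 28 members, adjusted p = 0.0440; adjusted p = 0.509 with an estimated correlation), and its call ended in 5 of the 6 fits that left out a library (adjusted p from 0.0760 to 0.244, aged replicate 1 excepted), by fry (adjusted p = 0.236) and with a replicate block (adjusted p = 0.0814). The glycolysis list was called higher (median 0.86 over 18 members, adjusted p = 0.0032; adjusted p = 0.440 with an estimated correlation and 0.124 by fry), with Eno1, an enolase gene, past over the list alone at 49.5 ± 22.8 and 248 ± 70.1 CPM.

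**Figure D2:**
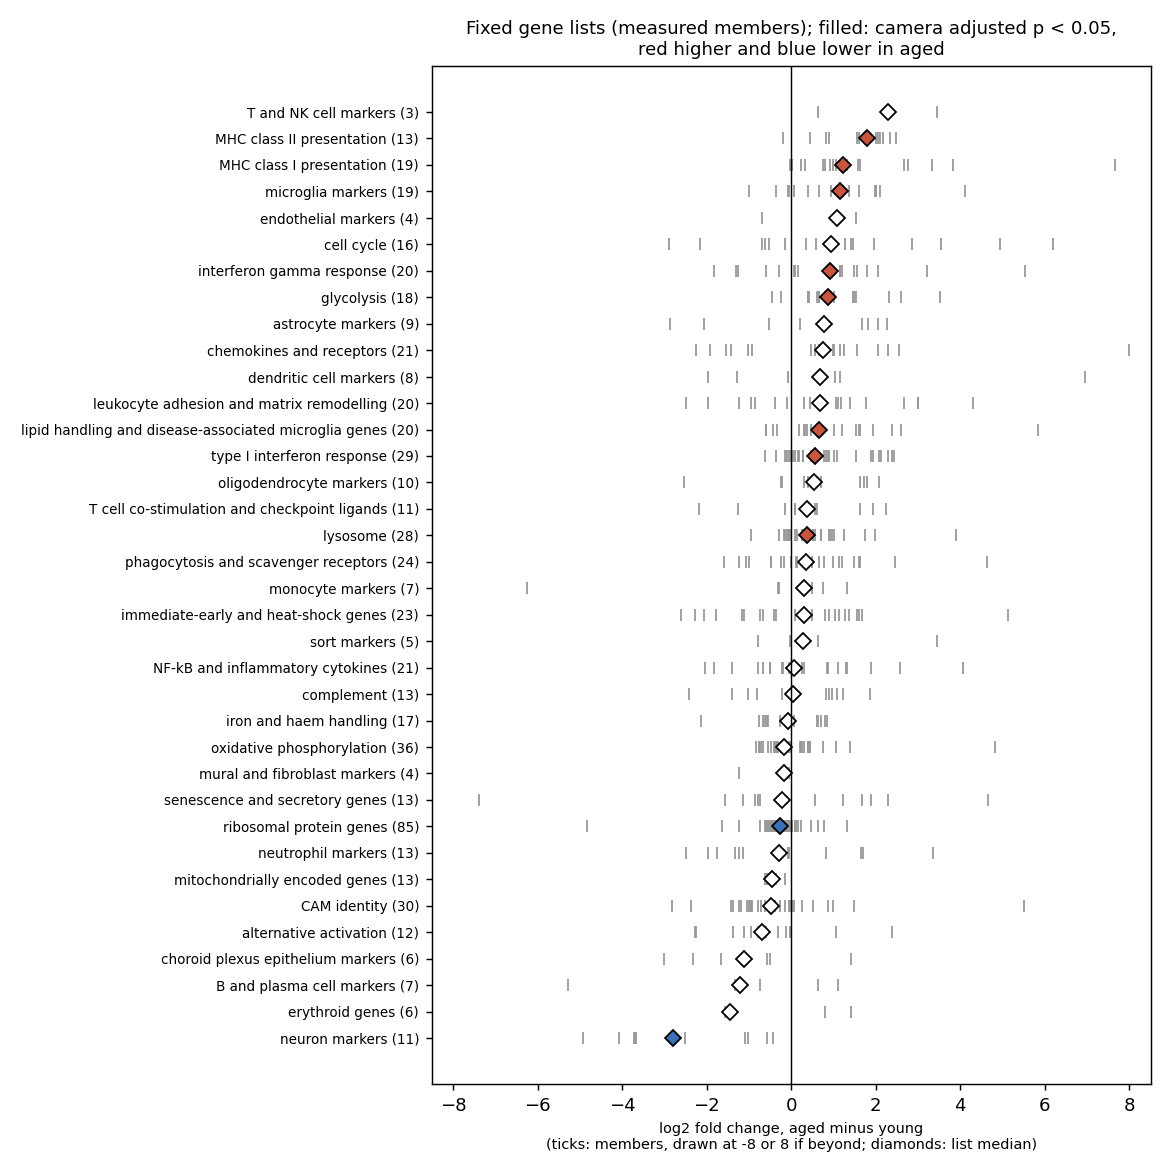
Fitted log2 fold changes, aged minus young, for the measured members (grey ticks) of the 36 fixed gene lists, with each list's median as a diamond. Filled diamonds mark the 8 lists called higher (red) and the 2 called lower (blue) by camera with the preset correlation. With an estimated correlation 0 of these lists were called.

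Neuron markers were called lower (median -2.80 over 11 members, camera adjusted p = 1.59e-05; adjusted p = 0.112 with an estimated correlation). All 11 fitted values were below 0, 0 members passed over the list alone, and levels were low, Meg3 being at 33.1 ± 26.3 and 1.96 ± 1.35 CPM. Ribosomal protein genes were called lower (median -0.27 over 85 members, adjusted p = 0.0189; adjusted p = 0.769 with an estimated correlation, 0.471 by fry and 0.0598 with a replicate block). That call rested on aged replicate 2 (adjusted p = 0.903 without it) and ended without any 1 of the young libraries (adjusted p from 0.0512 to 0.0760). Rps29 was at 3411 ± 824 and 2035 ± 1014 CPM. The share of counts from ribosomal protein genes was 5.70 ± 0.566% in young and 4.69 ± 1.37% in aged libraries (exact permutation p = 0.3, n = 3 each). Mitochondrially encoded genes took 11.1 ± 2.65% and 7.98 ± 2.93% of counts (exact permutation p = 0.2, n = 3 each), where the smallest p this design allows is 0.1. All 13 had fitted values below 0, and the list was not called (median -0.45, adjusted p = 0.0564).

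The remaining lists of macrophage genes were not called, with camera adjusted p-values of 0.0739 for alternative activation (median -0.70, Ccl24 past over the list alone), 0.172 for phagocytosis and scavenger receptors (0.35), 0.254 for NF-kB and inflammatory cytokines (0.06), 0.254 for leukocyte adhesion and matrix remodelling (0.67), 0.301 for iron and haem handling (-0.08), 0.331 for T cell co-stimulation and checkpoint ligands (0.38) and 0.459 for complement (0.05). Single members passed over these lists alone but not over all genes tested. Selplg, a selectin ligand, rose from 123 ± 48.3 to 780 ± 584 CPM. The galectin gene Lgals9 rose by 1.93 (SE 0.52) on the log2 scale, while Cd200r1, an inhibitory receptor, fell from 196 ± 141 to 43.5 ± 19.4 CPM. Slc40a1, the iron exporter ferroportin, fell from 159 ± 53.1 to 36.2 ± 5.71 CPM. The complement genes C1qb (1.22, SE 0.38) and C1qc (1.08, SE 0.44) did not pass. Lists of cell cycle (median 0.94, adjusted p = 0.0501), immediate-early and heat-shock genes (0.30, adjusted p = 0.986), senescence and secretory genes (-0.21, adjusted p = 0.831), oxidative phosphorylation (-0.16, adjusted p = 0.690) and sort markers (0.28, adjusted p = 0.831) were not called. For sort markers and senescence genes camera's direction was opposite in sign to both median and mean, for oxidative phosphorylation to the mean (0.06).

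Transcripts of blood and of other brain cells were found at uneven levels within both groups. Neutrophil markers summed to 37893, 12090 and 14560 CPM in young and 21701, 8064 and 25.8 CPM in aged libraries, and S100a8 was at 0.778 CPM in aged replicate 3 against at least 2867 CPM in every other library. Erythroid genes summed to 13809, 10100.4 and 30342 CPM and to 9886, 9102 and 114 CPM. Choroid plexus epithelium markers, led by Ttr, stood apart in young replicate 3 (11964 CPM) and aged replicate 3 (8062 CPM), and did not exceed 1432 CPM in the other libraries. These lists were not called (camera adjusted p = 0.131, 0.204 and 0.928, medians -0.29, -1.44 and -1.12, the last with camera's direction opposite in sign). Neither were dendritic cell markers (0.68, adjusted p = 0.0595), of which Siglech rose over the list alone from 619 ± 150 to 1387 ± 90.8 CPM, a gene also on the microglia list. Monocyte (median 0.31, mean and camera's direction below 0, mean -0.57, adjusted p = 0.690), B and plasma cell (-1.21, adjusted p = 0.433), astrocyte (0.78, adjusted p = 0.898) and oligodendrocyte markers (0.55, adjusted p = 0.301) were not called. Markers of T and NK cells (3 measured, median 2.29), endothelium (4, median 1.09) and mural cells and fibroblasts (4, median -0.18) were too few for a test.

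**Figure D3:**
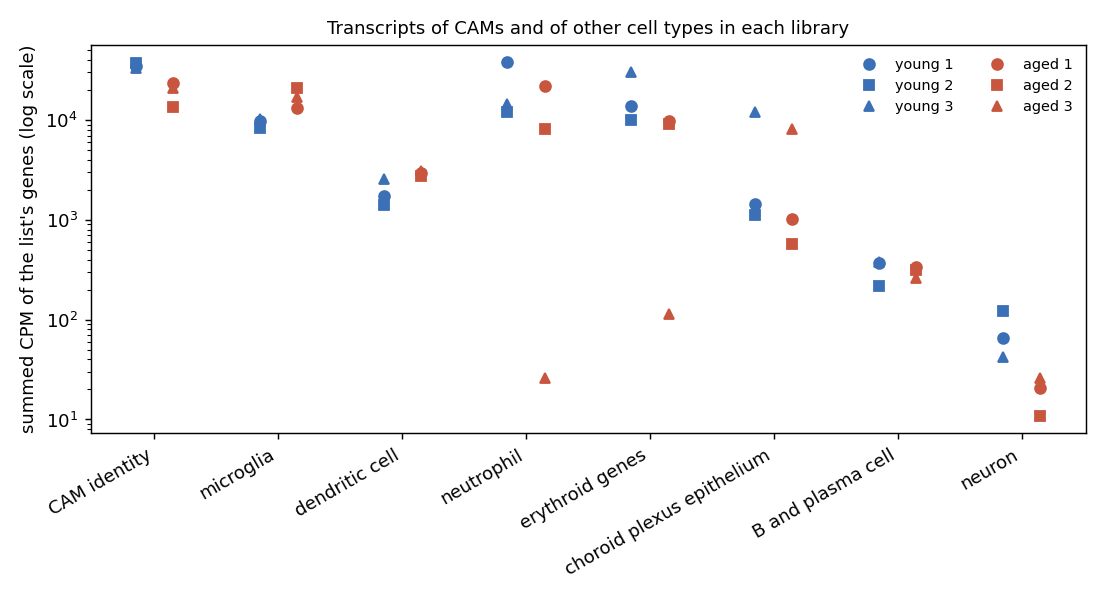
Summed CPM, on a log scale, of the genes of 8 marker lists in each of the 6 libraries (blue young, red aged, with the symbol giving the replicate). Summed CAM genes lie lower and microglia genes higher in each aged library than in any young one, and aged replicate 3 lies far below the others for neutrophil and erythroid genes.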

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

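The filter on a mean of at least 50 CPM was chosen after seeing the data; the other settings were planned. Genes called higher (1) and lower (0) became 270 and 187 in the DESeq2 Wald test, 51 and 11 with no low-count filter and 19 and 6 at a mean of at least 50 CPM. They were 0 and 0 in limma-voom (936 genes at an unadjusted p under 0.05) and with quality weights (954 genes). Of the DESeq2 calls, 75.1% had a library with 3 counts or fewer, and in simulated data DESeq2 made 145 false calls. Leaving out a library gave 0 to 2 genes higher and 0 to 1 lower, adding Cd209d without young replicate 3 and Ccdc152 without aged replicate 1. Other settings kept 1 and 0. The adjusted p of Cxcl13 ranged from 1.55e-35 with no filter to 0.117 in limma-voom.

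Lists called higher (8) fell to 0 with an estimated correlation and 3 by fry, and lay between 5 and 8 when a library was left out. Lists called lower (2) were 0 with an estimated correlation, 1 by fry, 4 with the filter of 10 CPM in 3 libraries, 5 at a mean of at least 50 CPM and 1 to 5 when a library was left out. In simulated data with class II genes raised 4-fold, the estimated correlation gave an adjusted p of 0.826 for that list and fry 0.158, so both missed a simulated change of that size. The simulated genes varied independently, while the real class II list had an estimated correlation of 0.482. The simulation therefore cannot tell low power from members that move together. Fry called class I, lipid handling and phagocytosis (adjusted p = 0.0430) higher and neuron markers lower. At 10 CPM in 3 libraries and at a mean of at least 50 CPM, CAM identity (adjusted p = 0.0110 and 0.00722), alternative activation (0.00964 and 0.00295) and mitochondrial genes (0.0142 and 0.00957) were called lower. Dendritic cell (0.0103 at 10 CPM), complement (0.0249 at 50 CPM) and cell cycle lists (0.0483 with DESeq2 size factors) were called higher, and neutrophil markers lower (0.0345 at 50 CPM). At 50 CPM, interferon gamma (0.238) and type I interferon (0.0588) lost their calls. Without aged replicate 1, CAM identity, mitochondrial, neutrophil and cell cycle lists gained calls, as did the neutrophil list without young replicate 2 and the mitochondrial and cell cycle lists without young replicate 3. The choroid plexus list changed direction without young replicate 2 (adjusted p = 0.0436, up to 0.889 without other libraries), as did the ribosomal list without aged replicate 2 (adjusted p = 0.903, down to 0.000495 without other libraries). The causes were not tested. Adjusted p-values of the class II list in the camera fits with the preset correlation ranged from 1.05e-06 to 0.0189.

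Pairing of the samples by replicate number was not shown, and the check, made over all tested genes, cannot exclude it. Same-numbered libraries correlated at -0.0097, -0.0257 and 0.0220 in their deviations from the group means, and only the libraries numbered 3 were each other's best partner. With a replicate block 1 gene was higher and 0 lower, 8 lists called higher became 6, without interferon gamma and lysosome, and 2 called lower became 1, without ribosomal protein genes.

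Of 102 named genes tested, Cxcl13 alone lost its call in 4 of 1616 alternative fits, 41 genes gained one in at least 1 fit, and 0 called values changed sign. In 65 fits, over 22 genes, a value changed sign with neither fit past the threshold. The median over tested genes was 0.23 in limma-trend on TPM, with its own filter and scale, against -0.02. The median biological coefficient of variation was 129% under 50 CPM, and what limited those genes was not tested.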

Other observations

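The filter on a mean of at least 50 CPM and all tests of explanations given here, except the splits of the libraries, were chosen after the results had been seen. That filter called 25 genes of 2185 tested, 19 higher and 6 lower, by edgeR. Besides class II and chemokine genes, the genes called higher included Ppt1, Scpep1, Ifngr1 and Tmem173. Ppt1, a lysosomal thioesterase, was at 164 ± 46.5 and 594 ± 43.8 CPM in young and aged libraries, and the serine carboxypeptidase gene Scpep1 at 87.4 ± 11.8 and 391 ± 111 CPM. Ifngr1, a chain of the interferon gamma receptor, was at 142 ± 23.7 and 596 ± 248 CPM, and Tmem173, which encodes the DNA-sensing adaptor STING, at 87.4 ± 18.1 and 355 ± 153 CPM. Cd81 (208 ± 19.5 and 899 ± 488 CPM), Gpx3, Nono, Samsn1 and Blnk were also higher. Tslp, a cytokine gene of barrier tissues, was lower, at 323 ± 43.0 and 89.0 ± 48.7 CPM. In that fit the adjusted p of Ppt1 was 0.00499 and of Tslp 0.0216, against 0.378 and 0.515 over all genes tested.

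Beyond Cxcl13, 2 of the 10 genes with the smallest p-values were nearly absent from young libraries. Lat2, an adaptor of immune receptors, was at 0.209 ± 0.335 and 82.0 ± 30.7 CPM, and Bco2, a carotenoid oxygenase, at 0.322 ± 0.311 and 40.7 ± 2.10 CPM, neither past the threshold over all genes tested (edgeR adjusted p = 0.378). Each overlaps another gene on the opposite strand, Rfc2 and Il18, so their reads are uncertain. The mean level of Rfc2 rose with that of Lat2 (3.70 and 47.3 CPM), while that of Il18 did not rise with that of Bco2 (140 and 99.0 CPM). The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The ages gave 1 called gene, 25 called genes at a mean of at least 50 CPM and 10 called lists, each as large in 1 split, and the highest of the other splits gave 0 genes, 0 genes and 8 lists. In a split that set young replicate 1 and aged replicates 2 and 3 against the rest, the class II list reached an adjusted p of 1.54e-05, smaller than by age.

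Higher class II genes may reflect age, which stayed open. B cells mostly lack the CD11b of the gate. Their markers summed to 373.5, 219.3 and 381.2 CPM in young and 334.9, 314.6 and 260 CPM in aged libraries, so the sum did not rise. Ighm alone was at 81.4 ± 6.39 and 176 ± 62.7 CPM. The median of the 7 measured markers lay 2.99 below that of the class II genes (-2.99 on the log2 scale, exact permutation p = 0.00108). This permutation takes genes as replicates and holds no spread between libraries, so it cannot exclude B cells as a source. Scaling, which shifts all genes of a library alike, was argued against by the medians themselves. The median log2 fold change was -0.02 over all genes tested and 1.79 over the class II genes. TMM sets the median over all genes near 0, so only the gap between these medians bears on scaling. The class II median lay 1.95 above that of 10000 random lists matched on mean level, 0 of them as high (permutation p = 0.0001). Camera had already called the class II list above other genes, and random lists take genes as independent, so this p added no support. A larger share of microglia in the aged libraries remained open. The class II median exceeded that of the microglia markers by 0.624 (permutation p = 0.298, over genes). This comparison cannot show microglia to be the source, since the class II level of microglia was not measured apart from that of CAMs. For dendritic cells the difference was -1.11 (exact permutation p = 0.0722, again over genes). With 8 measured markers, led by Siglech and Bst2 (735 ± 63.4 and 703 ± 306 CPM), this cannot be told apart from a rise as large as that of the class II genes.

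Lower CAM markers beside higher microglia markers could come from a larger share of microglia passing the gate. As the whole cause, dilution would lower by 1 factor the CAM markers that microglia lack. An F test of heterogeneity on edgeR's estimates took genes as independent. It gave p = 0.0283 over the CAM identity list (n = 30 genes) and p = 0.0289 without members that microglia also express (n = 25 genes). A choice of CAM-restricted markers, tested first, gave p = 0.0772 by the same test (n = 12 genes). With Cd209b, Cd209d, Cd209g and Timd4 added, the test gave p = 0.0236 (n = 16 genes). Cd209b, Cd209d and Timd4 had already been seen higher in each aged library, so adding them to mostly lower markers favoured heterogeneity in advance. The set of 25 genes holds them too. The outcome depended on the members, so the test could not decide on dilution as the whole cause. Dilution as the whole cause or a part of it, and a change within CAMs with age, stayed open.

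The absence of Cxcl13 from young libraries was set against random loss of transcripts at low input. Among 1106 other genes with an aged level within 2-fold of that of Cxcl13, each young library had 3 genes with 3 counts or fewer, and 2 genes, Lat2 and Cd209d, were so low in 2 young libraries, where independent losses would give 0.0243. Independent losses would give 2.21e-05 genes lost from all 3, which argues against independent loss as the source of the 0 counts of Cxcl13. Losses that strike a gene in several libraries, or an age difference in Lat2 and Cd209d as well, would both give the 2 genes. Loss of that shared kind stayed open, although 0 genes besides Cxcl13 were lost from all 3. A count of genes at 50 CPM or more in 3 libraries and at the floor in the other 3 gave 0 in the 9 other splits, but its value of 1 for the ages was set by the gene that prompted it. A higher level in aged CAMs, or a Cxcl13-expressing cell type present only in aged sorts, remained open and was not tested.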
